A study of Drosophila melanogaster with 30 samples.

How the data were processed

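Nuclear RNA was sequenced from outer photoreceptors of male Drosophila melanogaster, taken at day 30 from flies kept at 25 C with 12 h of light and 12 h of dark, per the labels' protocols. Outer photoreceptors are the cells of the fly eye that express the rhodopsin Rh1 (gene ninaE). Per the labels, an Rh1 driver expressed Gal4, which in turn drove a short hairpin RNA (shRNA) against 1 gene, and a GFP tag on the nuclear envelope allowed the nuclei to be enriched with an antibody. The labels' protocols give a column kit with DNase I for the RNA, 10 ng of RNA per library and a library kit with depletion of fly ribosomal RNA.

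The 30 libraries fell into 10 groups of 3 biological replicates. The shRNA of 9 groups was directed against Spt5, dom, Spt6, TH1, Cdk12, Taf1, Top1, Trl or cnc, and that of the control group against LexA, a bacterial gene that flies lack. Groups and replicate numbers were taken from the sample titles. The genotype labels of Top1, TH1, Taf1, Spt6, Spt5 and Cdk12 count upward over the replicates, so that Spt5 replicate 2 carries the genotype label of Spt6, and they were not used.

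Each deposited file held whole-number counts of reads per gene for 1 library. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.39, aligned them with HISAT2 to the build BDGP6 and counted them with HTSeq. The strand setting, the counted feature type and the annotation release were not given in the sources used here. Reads of a gene and of a gene that overlaps it on the other strand could therefore not be told apart, and near-identical copies such as the Hsp70 genes could share or lose reads. Of the 17807 gene rows, 17710 had a symbol in the reference annotation, and the gene positions printed are those of that annotation for BDGP6. The files themselves hold no positions.

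Each file ended with 5 summary rows, for reads outside annotated features, ambiguous, of low quality, not aligned or aligned to several places. These rows and the rows of transgenes (Gal4, GFP and, in some files, LacZ and a Clk construct) stayed out of library sizes and tests. The summary rows held between 51.8% and 74.6% of all reads of a library. The files of Spt5 and Cdk12 lacked the LacZ and Clk rows, while the LexA files had them. Depth was between 4064250 and 18024440 gene counts per library. Reads carry no molecular identifiers, so the precision that depth gives covers counting error only.

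Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for gene lists. Genes passed edgeR's filter by expression with a minimum count of 10 and a minimum total of 15, which left 14888 genes. Libraries were scaled by the trimmed mean of M values (TMM), and all 30 libraries entered 1 fit with a mean per group. Each knockdown was compared with LexA, and Spt5 with dom, by the two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene comes from this test unless another is named. The standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM values, counts scaled to a common library size, were computed here with edgeR from TMM library sizes, with a prior count of 2 on the log2 scale.

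The tests, the alternatives, 27 gene lists and the rule for naming genes were chosen before the data were examined. In the comparisons of Spt5 and dom with LexA the rule named the target gene and the 8 genes with the largest change in each direction. These had to be called, to lie beyond every LexA library in all 3 knockdown libraries, to have an average log2 CPM of at least 3 and to carry a symbol that is not a bare CG or CR number and does not start with asRNA, lncRNA, snoRNA, scaRNA, tRNA, mir or snRNA. The rule also named up to 4 members of each list that moved, by smallest adjusted p. In the other comparisons it named the target, up to 4 genes in each direction and up to 3 members of each called list. ninaE and the 9 targets were named wherever they were called.

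The lists covered phototransduction, the rhabdomere and apical membrane, photoreceptor synapse and excitability, the circadian clock, and markers of inner photoreceptors, of cone, pigment and corneal cells, of glia, of other neurons, of muscle and of fat body and hemocytes. Other lists held marker genes of transgenic lines, heat shock proteins and chaperones, the unfolded protein response, oxidative stress and glutathione, innate immunity, DNA damage and cell death, and autophagy and lysosome. The rest held transcription initiation and elongation factors, the Tip60 and SWR1 type remodelling complex, cytosolic ribosomal proteins, nuclear and mitochondrially encoded proteins of oxidative phosphorylation, the proteasome, glycolysis, and the longest, the shortest and the single exon genes. Of the symbols listed, 13 matched no row. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 27 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members called were counted after adjustment over all genes tested and again "adjusted over the list alone".

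The procedure was tested on simulated counts with the means and library sizes of these libraries, 14266 genes after the filter and known changes in a simulated Spt5 group. It called 56.9% of 65 genes changed 4-fold, 15.4% of 65 changed 2-fold and 1.5% of 67 changed 1.5-fold. Among genes with an average log2 CPM of at least 3, it called 100% of 31 genes changed 4-fold and 35.7% of 28 changed 2-fold. No call was an unchanged gene, and a simulated dom group without changes gave 0 calls. Simulated genes varied independently, without a factor common to a whole library and without a library that stands apart. False calls from such effects were therefore not measured.

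The alternatives tried were DESeq2's size factors, DESeq2's Wald test (version 1.42.0), no filter on low counts, ribosomal RNA and mitochondrial genes left out, the replicate number as a block, a fit of only the 6 libraries compared, the mean of the other 8 knockdowns in place of LexA, and each replicate left out in turn. A covariate for the log2 ratio of reads outside annotated features to gene counts (the background covariate), and the Cdk12 libraries as the reference for Spt5, were chosen after seeing the data. The correlation and covariance of comparisons that share the LexA libraries were set beside 20 simulated draws of unchanged groups. Coding variants, splicing and ageing were not analysed here.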

Results

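Nuclear RNA of outer photoreceptors was measured at day 30 in 10 groups of 3 libraries. The series title names Spt5 and dom as transcription regulators whose knockdown in photoreceptors goes with degeneration of the retina. The question that the counts address is which genes differ in these nuclei when Spt5, dom or each of 7 other regulators is targeted. Gene counts per library lay between 5413749 and 7184260 in LexA, 7535919 and 14659278 in Spt5, and 8585176 and 13722049 in dom. Over all 30 libraries they lay between 4064250 (Trl replicate 2) and 18024440 (cnc replicate 2).

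Libraries differed in reads that lay outside annotated features, from 55.4 per 100 gene counts in Spt5 replicate 1 to 171.7 in Trl replicate 2. The first principal component of log2 CPM held 41.3% of the variance and followed the log2 of this ratio over the 30 libraries. Pearson's r was -0.87 and Spearman's rho -0.87, each with a permutation p of 1.0e-05, the smallest that the resamples can give. Without the 2 libraries farthest from the median, r was -0.89. It was -0.9 within the 24 libraries of the 8 groups that share a file layout and -0.9 within the 6 libraries of Spt5 and Cdk12.

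**Figure D1:**
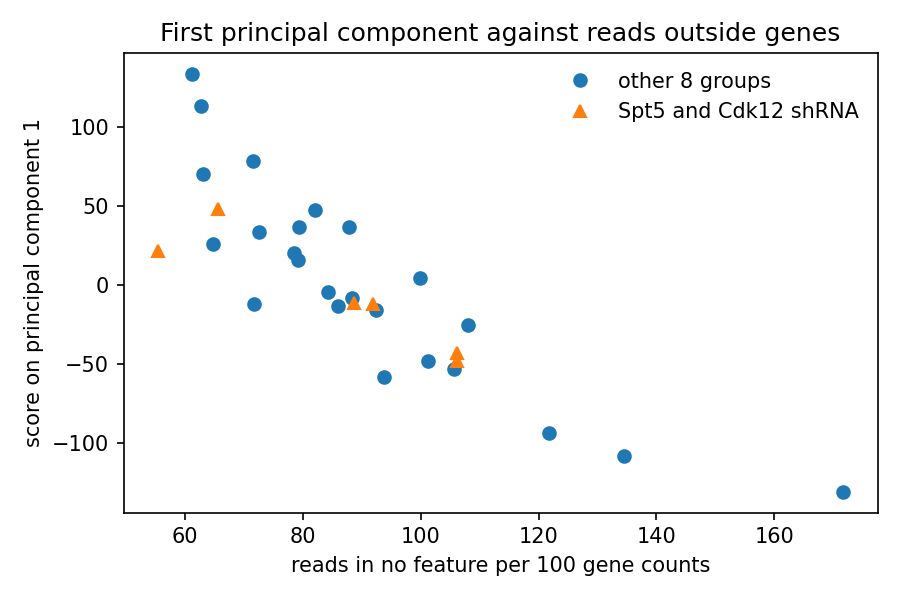
Score on the first principal component of log2 CPM (vertical axis) against reads in no annotated feature per 100 gene counts (horizontal axis), 1 point per library. Triangles are the 6 libraries of Spt5 and Cdk12, circles the 24 of the other groups, and r over all 30 was -0.87 against the log2 of the ratio.

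The targeted gene was read first in every group. No target was called lower than in LexA, and the knockdown labels could not be checked from nuclear RNA in this way. The largest decreases were those of Taf1 (log2 fold change -0.41, SE 0.26, adjusted p 1), TH1 (-0.35, SE 0.27, adjusted p 1) and Spt5 (-0.34, SE 0.18, adjusted p 0.24), with n = 3 per group. Spt5, a subunit of the elongation factor DSIF, stood at 64.3, 56.1 and 58.3 CPM in its knockdown libraries and at 74.4, 84.3 and 68.3 CPM in LexA, so all 3 lay below every LexA library. It was called with the background covariate (-0.44, adjusted p 0.036) and with DESeq2 (-0.39, adjusted p 0.022). dom, the ATPase of a chromatin remodelling complex that exchanges histone variants, stood at 241, 362 and 366 CPM against 370, 348 and 366 CPM (log2 fold change -0.16, SE 0.2, adjusted p 0.73). Top1 (-0.21, SE 0.18, adjusted p 0.87), Spt6 (0.12, SE 0.21, adjusted p 0.95), Cdk12 (0.16, SE 0.19, adjusted p 0.93) and cnc (0.05, SE 0.19, adjusted p 0.97) were not called.

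Trl, the GAGA factor, was at 14, 15.5 and 21.9 CPM in the library group labelled Trl and at 8.67, 12.4 and 11.2 CPM in LexA (log2 fold change 0.67, SE 0.27, adjusted p 0.13). It was called higher with DESeq2 (0.84, adjusted p 0.038) and against the other 8 knockdowns (0.85, adjusted p 0.0064). The estimate for Taf1 rested on LexA replicate 3, at 562 CPM against 267 and 258 CPM in the other LexA libraries, and its leave-one-out values ran from -0.6 to 0.06. An shRNA can lower a messenger in the cytoplasm while nuclear RNA changes less, and protein levels were not measured.

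**Figure D2:**
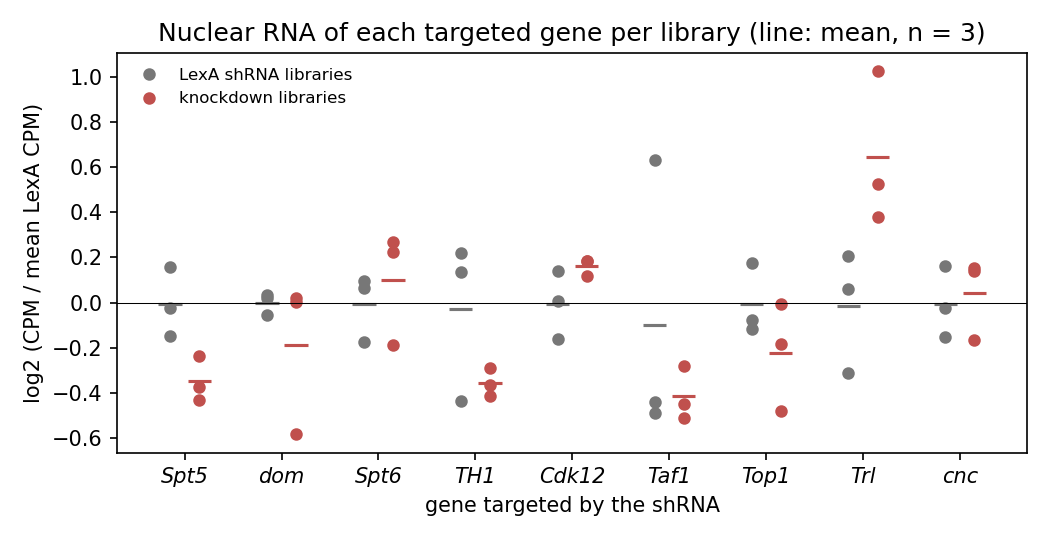
Nuclear RNA of each targeted gene as log2 of its CPM over the mean LexA CPM (vertical axis), with 3 LexA libraries in grey and 3 knockdown libraries in red for each target (horizontal axis). Horizontal lines are means. The log2 fold changes of the fit ran from -0.41 (Taf1) to 0.67 (Trl), and none passed the test.

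Knockdown groups differed in how many of the 14888 tested genes were called against LexA. The counts were 2450 for Spt5, 1543 for dom, 379 for Trl, 64 for Top1, 43 for cnc, 30 for TH1, 29 for Cdk12, 22 for Taf1 and 16 for Spt6.

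**Figure D3:**
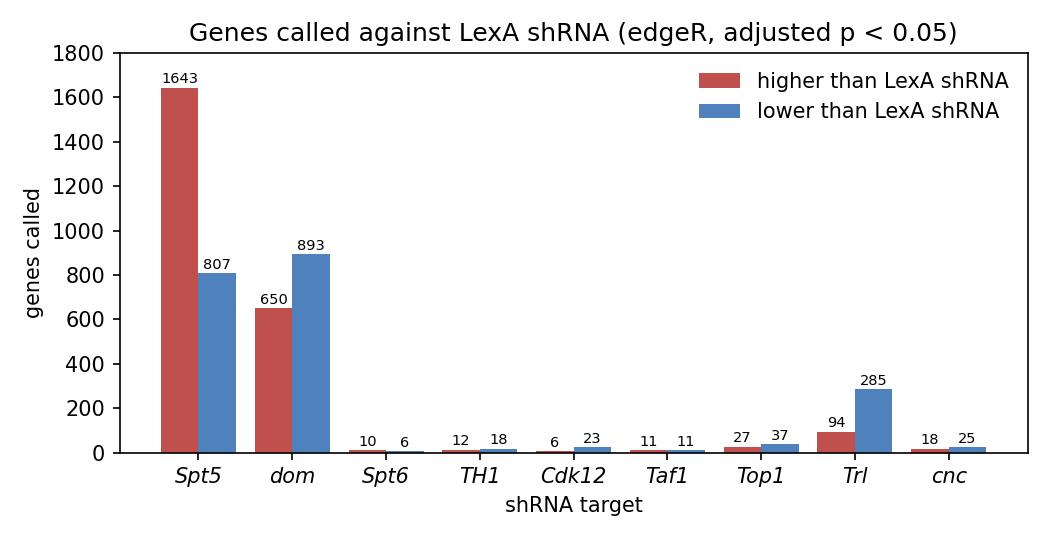
Genes called higher (red) and lower (blue) than LexA shRNA in each knockdown group, as a count of genes (vertical axis) per target (horizontal axis), by edgeR at an adjusted p under 0.05. Spt5 has 1643 higher and 807 lower, dom 650 and 893, Trl 94 and 285.

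In Spt5 against LexA, genes of the light response of photoreceptors were lower and markers of several other cell types higher, mostly through Spt5 replicates 1 and 2. Their phototransduction medians were -1.29 and -1.36 and those of other neurons 2 and 1.73, while replicate 3 lay nearer LexA (-0.27 and 0.04). Of the 30 tested phototransduction genes, 17 fell and 3 rose, with a median log2 fold change of -0.92 (23 and 3 adjusted over the list alone). Those that fell included Ggamma30A (log2 fold change -1.49, SE 0.34, adjusted p 0.0049), a G protein subunit of the cascade, and, chosen after their values were seen, the channel gene trpl (-1.57, SE 0.37) and the kinase gene inaC (-1.56, SE 0.36). Without Spt5 replicate 3 the last pair were at -2.37 and -2.52. Those that rose were santa-maria (1.9, SE 0.36), a receptor for carotenoid uptake, the lipid phosphatase laza (1.61, SE 0.37) and the phospholipase Pld (1.1, SE 0.24). ninaE itself had a log2 fold change of -0.48 (SE 0.2, adjusted p 0.11). Camera called the list lower (adjusted p 5.5e-10), with adjusted p = 0.21 with an estimated correlation.

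The lists of the rhabdomere and of synapse and excitability were lower as well. Of 18 genes of the rhabdomere, the membrane stack that holds rhodopsin, 11 fell (median -0.81, 13 adjusted over the list alone), among them chp (-1.42, SE 0.39, adjusted p 0.013, and -2.53 without Spt5 replicate 3) and Rab6 (-1, SE 0.23, adjusted p 0.0051). Of 26 genes of synapse and excitability, 11 fell and 3 rose (median -0.74, 21 and 3 adjusted over the list alone). CarT, a carcinine transporter of photoreceptors, fell (-1.53, SE 0.32, adjusted p 0.0037), as did the active zone genes Rim (-1.01, SE 0.25) and brp (-0.98, SE 0.25), while the channel gene Ih rose (1.56, SE 0.36). Camera gave adjusted p 2.1e-08 and 6.6e-09 for these lists, with adjusted p = 0.21 and 0.23 with an estimated correlation. Of 15 clock genes 3 fell (dco, sgg and jet, median 0 over the list, 3 adjusted over the list alone), and camera did not call that list (adjusted p 0.1).

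Markers of other neurons rose in 15 of 18 genes (median 1.51, 16 adjusted over the list alone), among them the transmitter transporters VAChT (1.56, SE 0.3, adjusted p 0.0029), VGlut (1.67, SE 0.33) and VGAT (1.73, SE 0.35). Of 17 glial markers 13 rose and 1 fell (median 1.16, 13 and 1 adjusted over the list alone), led by the glial transcription factor repo (1.67, SE 0.33, adjusted p 0.0034). Markers of inner photoreceptors rose in 8 of 14 and fell in 2 (median 0.97, 9 and 2 adjusted over the list alone), including the rhodopsins Rh6 (1.78, SE 0.34), Rh3 (1.35, SE 0.31) and Rh4 (1.25, SE 0.31). Cone, pigment and corneal cell markers had 7 higher and 1 lower of 17 (median 0.89, 9 and 1 adjusted over the list alone), with Crys (2.24, SE 0.5), a lens protein gene, among them. Fat body and hemocyte markers had 11 higher of 22 (median 1.16, 12 higher and 2 lower adjusted over the list alone), with Lsp2 (2.21, SE 0.37) and srp (1.62, SE 0.34). Muscle markers were called in 2 of 23, both lower (Tm1 and Zasp52, median 0.13), and camera did not call them (adjusted p 0.6). Camera called the others with adjusted p 3.6e-10 for other neurons, 5.0e-06 for glia, 0.0014 for inner photoreceptors, 0.012 for cone, pigment and corneal cells and 2.3e-04 for fat body. With an estimated correlation these were adjusted p = 0.21, 0.24, 0.21, 0.21 and 0.21.

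Ribosomal protein genes and some genes of stress, immunity and glycolysis were higher in Spt5 as well. Of 85 cytosolic ribosomal protein genes 76 rose (median 1.37, 78 adjusted over the list alone), such as RpLP1 (1.81, SE 0.36, adjusted p 0.0034) and RpL28 (1.73, SE 0.35). Camera gave adjusted p 6.5e-32, and adjusted p = 0.21 with an estimated correlation. Heat shock genes rose in 6 of 21 (median 1.07, 7 adjusted over the list alone), with Hsp27 (4.02, SE 0.92, adjusted p 0.0049), Hsp68 (3.41, SE 0.89) and Hsp23 (2.56, SE 0.67). Innate immunity had 14 higher of 43 (median 0.98, 14 adjusted over the list alone), led by pirk (3.11, SE 0.56, adjusted p 0.0022), a regulator of the Imd pathway. Glycolysis had 7 higher of 14 (median 0.92, 10 adjusted over the list alone) with Pgi (1.38, SE 0.32), and oxidative stress 8 higher and 1 lower of 38 (median 0.64, 14 and 1 adjusted over the list alone), where Cyp6g1 rose (1.77, SE 0.37) and Cat fell (-1.29, SE 0.3). Camera called heat shock (adjusted p 2.3e-04), immunity (3.4e-05), glycolysis (1.9e-04) and oxidative stress (9.5e-04). With an estimated correlation these were adjusted p = 0.34, 0.21, 0.36 and 0.36.

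Camera also called mitochondrially encoded proteins higher (median 0.8, 3 of 12 higher, adjusted p 0.0014, and adjusted p = 0.44 with an estimated correlation), but its median was -0.23 against Cdk12, which itself had 1.18 against LexA. Nuclear encoded oxidative phosphorylation was also called higher (median 0.41, 1 of 82 higher, adjusted p 0.0068, and adjusted p = 0.64 with an estimated correlation). The longest genes had 478 higher and 188 lower of 1480 (median 0.26, 565 and 275 adjusted over the list alone, adjusted p 0.013, and adjusted p = 0.63 with an estimated correlation). Their medians in Spt5 replicates 1, 2 and 3 were 0.39, 0.28 and -0.08. Camera did not call the unfolded protein response (adjusted p 0.55), DNA damage and cell death (0.99), autophagy and lysosome (0.13), transcription factors (0.29), the Tip60 and SWR1 type complex (0.7), the proteasome (0.71), the marker genes of transgenic lines (0.73), the shortest genes (0.17) or the single exon genes (0.55). Called members of these included the pro-apoptotic gene hid (1.23, SE 0.27), Drice (-0.89, SE 0.23), Thor (1.01, SE 0.28), MRG15 (-0.94, SE 0.24), Tip60 (-0.64, SE 0.2), Ctr9 (0.55, SE 0.19) and Atg16 (-0.69, SE 0.18). The line marker gene v was also called higher (1.11, SE 0.26, adjusted p 0.0057). Thor turned lower with the Cdk12 reference.

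By the naming rule, the increases in Spt5 were led by Hsp68, Hsp70Ba (3.02, SE 1.02, adjusted p 0.041), Hsp26 (2.89, SE 0.86), the monooxygenase Fmo-2 (2.62, SE 0.45), a 28S ribosomal RNA pseudogene (28SrRNA-Psi:CR45855, 2.61, SE 0.84), the immune peptide BomS6 (2.48, SE 0.41), Pepck2 (2.46, SE 0.41) and the purine synthesis gene Prat2 (2.45, SE 0.41). The pseudogene and Hsp70Ba have close copies and are uncertain. The decreases were led by Cks30A (-2.9, SE 0.78), Crg-1 (-2.83, SE 0.56), Csgalnact (-2.57, SE 0.24), the nuclear receptor Hr38 (-2.22, SE 0.73), FarO (-2.08, SE 0.43), the innexin Inx7 (-2.02, SE 0.47), the neuropeptide gene Capa (-1.85, SE 0.45) and DCX-EMAP (-1.77, SE 0.37). Cks30A stood at 113 CPM in LexA replicate 3 and at 17.5 and 10.5 CPM in the other LexA libraries.

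Against LexA, 2450 genes were called in Spt5, 1643 higher and 807 lower (edgeR). Spt5 replicate 3 differed from its group mates: beside the medians given above, its median for glia was 0.08 against 1.55 and 1.37, and for ribosomal proteins 0.38 against 1.77 and 1.7. The count was 3726 without Spt5 replicate 3, 244 without Spt5 replicate 1, 593 without Spt5 replicate 2 and 1089 without LexA replicate 2, while a fit of only the 6 libraries gave 2 and the Cdk12 reference 1003. The files of Spt5 and Cdk12 differed from all others in layout and in multiply aligned reads (59.2 to 94.5 per 100 gene counts in Spt5, 72.9 to 82.6 in Cdk12, 12.8 to 33 in the other 24 libraries). Cdk12 with this layout had 29 calls against LexA.

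**Figure D4:**
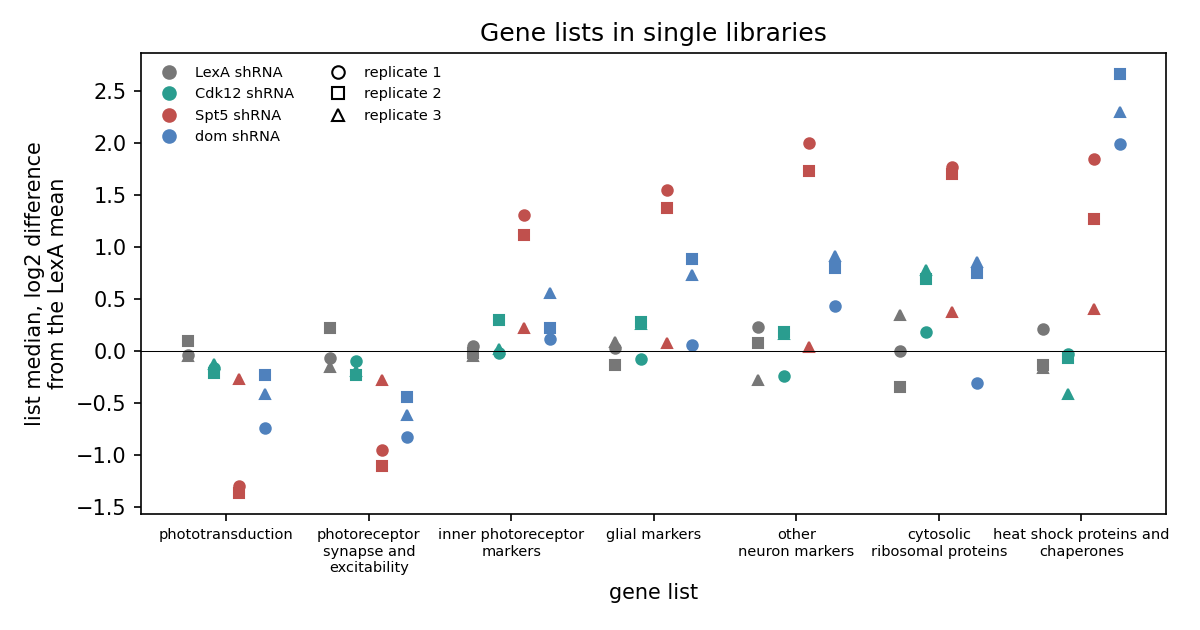
Median log2 difference from the LexA mean (vertical axis) of 7 gene lists (horizontal axis) in each library of LexA, Cdk12, Spt5 and dom, with a marker shape per replicate. Spt5 replicates 1 and 2 lie at -1.29 and -1.36 for phototransduction and at 2 and 1.73 for other neurons, and replicate 3 at -0.27 and 0.04.

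In the dom libraries, heat shock genes were higher and genes of the photoreceptor synapse lower than in LexA. Of 21 heat shock and chaperone genes 10 rose (median log2 fold change 2.35, 17 higher and 1 lower adjusted over the list alone). They included Hsp23 (5.41, SE 0.69, adjusted p 5.3e-06), at 27.2, 60.3 and 39.1 CPM against 1.62, 0.531 and 0.789 CPM in LexA, Hsp26 (4.44, SE 0.89), Hsp27 (3.98, SE 0.91) and the stress-induced noncoding RNA lncRNA:Hsromega (1.77, SE 0.35). Of 26 genes of synapse and excitability 13 fell and 1 rose (median -0.64, 14 and 1 adjusted over the list alone), among them the calcium channel gene cac (-1.21, SE 0.23, adjusted p 8.9e-04) and the active zone genes Rbp (-1.12, SE 0.23), Rim (-1.17, SE 0.25) and unc-13 (-1.18, SE 0.25). Camera gave adjusted p 7.8e-09 for heat shock and 1.7e-07 for the synapse. With an estimated correlation these were adjusted p = 0.63 and 0.69.

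Phototransduction genes had 4 lower and 1 higher of 30 in dom (median -0.48, 9 and 3 adjusted over the list alone). Gprk1 (-1.02, SE 0.19, adjusted p 9.3e-04), a G protein-coupled receptor kinase, the rhodopsin phosphatase rdgC (-1.34, SE 0.36) and Galphaq (-1.06, SE 0.3) fell and santa-maria rose (1.36, SE 0.36), while ninaE had a log2 fold change of 0.24 (SE 0.2, adjusted p 0.56). Rhabdomere genes had 2 lower, kst (-1.37, SE 0.28) and Patj (-0.76, SE 0.2), and 1 higher, Act5C (1.33, SE 0.32), of 18 (median -0.44). Clock genes had 4 lower of 15 (median -0.36), CkIIbeta (-1.02, SE 0.19), jet, cyc and sgg. Transcription factors had 4 lower and 2 higher of 31 (median -0.35), such as lilli (-1.05, SE 0.21) and Trf2 (0.9, SE 0.18). Adjusted over the list alone these were 4 lower and 1 higher, 4 lower and 1 higher, and 10 lower and 2 higher. Camera called phototransduction (adjusted p 0.005), rhabdomere (0.0072), clock (0.017) and transcription factors (0.0034), each with adjusted p = 0.69 with an estimated correlation.

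Some genes of glycolysis, immunity and oxidative stress rose in dom. Glycolysis had 5 higher of 14 (median 0.77, 6 adjusted over the list alone), led by lactate dehydrogenase, Ldh (4.71, SE 0.48, adjusted p 1.2e-07), at 128, 179 and 139 CPM against 4.87, 5.14 and 7.1 CPM in LexA, and by Ald1 (1.21, SE 0.3). Innate immunity had 6 higher of 43 (median 0.59, 6 adjusted over the list alone), with PGRP-LC (1.32, SE 0.23), the receptor of the Imd pathway, and its NF-kappaB factor Rel (1.4, SE 0.32). Oxidative stress had 5 higher of 38 (median 0.73, 5 adjusted over the list alone), with ref(2)P (1.76, SE 0.29) and Trxr1 (1.08, SE 0.3). Mitochondrially encoded proteins had 2 higher of 12 (median 0.92, 3 adjusted over the list alone), glia 2 higher of 17 (median 0.7, 6 higher and 1 lower adjusted over the list alone) and other neurons 2 higher of 18 (median 0.72, 3 adjusted over the list alone). Camera called glycolysis (adjusted p 1.1e-04), immunity (0.017), oxidative stress (0.005), mitochondrial proteins (0.005), glia (0.017) and other neurons (0.0022), each with adjusted p = 0.69 with an estimated correlation. In dom replicate 1 the medians were near LexA for glycolysis (0.08, against 1.01 and 1 in replicates 2 and 3), glia (0.06, against 0.88 and 0.73) and mitochondrial proteins (0.21, against 1.08 and 1.42). Ribosomal proteins were called by camera (median 0.5, adjusted p 0.0022, and adjusted p = 0.87 with an estimated correlation), with 0 of 85 members called by edgeR, 1 by DESeq2 and 3 at an unadjusted p under 0.05, and medians of -0.31, 0.75 and 0.86 in the 3 libraries.

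Camera did not call the other lists in dom: inner photoreceptors (adjusted p 0.47), cone, pigment and corneal cells (0.65), muscle (0.28), fat body and hemocytes (0.62), marker genes of transgenic lines (0.58), the unfolded protein response (0.45), DNA damage and cell death (0.45), autophagy and lysosome (0.52), the Tip60 and SWR1 type complex (0.47), nuclear encoded oxidative phosphorylation (0.88), the proteasome (0.58), and the longest (0.62), the shortest (0.58) and the single exon genes (0.47). Within them 4 of 17 cone, pigment and corneal cell markers fell, g (-1.29, SE 0.25), ca (-0.78, SE 0.21), lt (-0.52, SE 0.15) and st (-0.97, SE 0.29), while the list had a median of 0.29. Parp1 (-1.35, SE 0.22) fell too, and Gadd45 (2.1, SE 0.32), Diap1 (1.4, SE 0.21), cathD (1.77, SE 0.34), Thor (1.44, SE 0.28) and Xbp1 (0.87, SE 0.23) rose.

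By the naming rule, the increases in dom were led by Ldh, Hsp70Ba (4.56, SE 1.06), Hsp26, tej (4.3, SE 0.41), a gene of the germline piRNA pathway, the sulfotransferase St3 (3.77, SE 0.33), the small GTPase Rgk1 (3.69, SE 0.21, adjusted p 1.6e-12), the collagen gene Mp (3.66, SE 0.37) and Hsp68 (3.64, SE 0.89). Rgk1 stood at 915, 1430 and 1130 CPM against 75.5, 99.4 and 93.1 CPM in LexA. The decreases were led by the inositol phosphate kinase Ipk1 (-2.89, SE 0.37, adjusted p 6.4e-06), Oseg4 (-2.43, SE 0.34), Csgalnact (-2.4, SE 0.24), Cib2 (-2.29, SE 0.38), stum (-2.13, SE 0.32), inaF-D (-1.93, SE 0.55), the calcium channel gene Ca-alpha1D (-1.92, SE 0.36) and dpr21 (-1.9, SE 0.37). The test called 1543 genes, 650 higher and 893 lower (edgeR). The count was 851 without dom replicate 2, 818 without dom replicate 3, 973 without LexA replicate 1 and 648 without LexA replicate 2, and it was 2400 with DESeq2 and 2565 in a fit of only the 6 libraries.

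Spt5 and dom were called the same way in 495 genes, 229 higher and 266 lower in both, and opposite ways in 32. Shared genes included Hsp68, Hsp70Ba, Hsp26 and Pepck2 (higher) and Ipk1 (lower). Ipk1 had -1.57 (SE 0.36) in Spt5, and Pepck2 1.95 (SE 0.41) in dom. Independent lists of these sizes would share 71.7 higher and 48.4 lower genes. Over 6492 genes with an average log2 CPM of at least 3, the correlation of log2 fold changes was 0.58 (0.516 for simulated unchanged groups). Their covariance was 0.332 (0.0479 simulated), across genes, which are not independent replicates. The simulated groups held no factor common to a whole library, so they may understate what shared controls give. Between Spt5 and the other knockdowns the correlation ran from 0.23 (Taf1) to 0.64 (Top1) and the covariance from 0.068 (Taf1) to 0.223 (Top1). The correlation was thus not particular to Spt5 and dom. Both comparisons use the same 3 LexA libraries, which are too few to split, so part of the excess may come from the shared controls. The count of genes changed the same way, Spt5 and dom, was 74 without Spt5 replicate 1, 116 without Spt5 replicate 2, 1081 without Spt5 replicate 3, 269 and 220 without dom replicates 2 and 3, 259 and 79 without LexA replicates 1 and 2, and 2 in fits of only the 6 libraries of each comparison.

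Compared directly, Spt5 and dom differed in 1219 genes, 511 higher and 708 lower in Spt5 (edgeR). Lower in Spt5 were tej (-5.03, SE 0.41, adjusted p 2.6e-09), the RNA methyltransferase gene Mettl3 (-4.63, SE 0.41), Ldh (-4.16, SE 0.45), Mettl4 (-3.32, SE 0.34) and ninaE (-0.72, SE 0.2, adjusted p 0.024). Higher in Spt5 were the pseudogene 28SrRNA-Psi:CR45855 (2.61, SE 0.83), Lsp2 (2.51, SE 0.38), BomS6 (2.35, SE 0.39) and tobi (2.18, SE 0.35). Ribosomal protein genes had 18 higher of 85 (median 0.91, 60 adjusted over the list alone), phototransduction 7 lower and 1 higher of 30 (median -0.34, 9 and 2 adjusted over the list alone), and heat shock 3 lower of 21 (median -0.62, 3 adjusted over the list alone), with Hsp23 at -2.84 (SE 0.56) and Arr2, a photoreceptor arrestin, at -1.2 (SE 0.25). Camera gave adjusted p 9.7e-18, 0.0029 and 0.019, each with adjusted p = 0.79 with an estimated correlation. Camera also called markers of other cell types higher in Spt5 than in dom: other neurons (median 0.77, adjusted p 0.0029), cone, pigment and corneal cells (0.67, 0.003), fat body and hemocytes (0.71, 0.0029), glia (0.46, 0.032) and inner photoreceptors (0.46, 0.032). It called the rhabdomere (-0.41) and the shortest genes (-0.29) lower and nuclear encoded oxidative phosphorylation (0.28) and the longest genes (0.34) higher. These 9 lists had adjusted p = 0.79 with an estimated correlation, except cone, pigment and corneal cells with 0.32. For other neurons and glia the difference rested on Spt5 replicates 1 and 2. Against LexA, replicate 3 had medians of 0.04 and 0.08, where the dom libraries had 0.43, 0.8 and 0.91 for other neurons and 0.06, 0.88 and 0.73 for glia. Its phototransduction median (-0.27) lay within those of dom (-0.74, -0.23 and -0.41). Of the 323 different genes of the 10 lists called (those by length left out), 30 were higher and 15 lower, and 78 and 17 adjusted over the list alone. The count was 2849 without Spt5 replicate 3, 653 and 624 without Spt5 replicates 1 and 2, 705 without dom replicate 2, 1938 with DESeq2 and 369 in a fit of only the 6 libraries.

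In the Trl libraries more of the called genes were lower than higher with TMM. They included the rhodopsin chaperone gene ninaA (-1.49, SE 0.29, adjusted p 0.0078), ninaB (-0.86, SE 0.18) and Pis (-0.87, SE 0.23), 3 of 30 phototransduction genes (median -0.68, 9 lower and 1 higher adjusted over the list alone). Of 31 transcription factors 5 fell (median -0.48, 17 lower and 1 higher adjusted over the list alone), among them Spt5 (-0.91, SE 0.19, adjusted p 0.013) and Taf1 (-1.11, SE 0.26, adjusted p 0.03). The Taf1 value may rest in part on LexA replicate 3, which stood far above the other LexA libraries for this gene. Of 30 autophagy and lysosome genes 5 fell (median -0.47, 9 adjusted over the list alone), with Npc2a (-1.3, SE 0.27) and Atg14 (-0.92, SE 0.22). Hsp70Bc (4.86, SE 1.15) and Hsp70Ba (3.82, SE 1.04) rose, 2 of 21 heat shock genes (median 0.91, 10 higher and 1 lower adjusted over the list alone), and the list's medians were 0.92, -0.49 and 0.93 in Trl replicates 1, 2 and 3. Camera gave adjusted p 1.4e-06, 5.5e-07, 1.2e-07 and 0.04 for these lists, and adjusted p = 0.38, 0.38, 0.38 and 0.64 with an estimated correlation. It also called the rhabdomere (median -0.64), synapse and excitability (-0.54), the clock (-0.53), the unfolded protein response (-0.49), the proteasome (-0.45), ribosomal proteins (-0.37), oxidative phosphorylation (-0.32), the Tip60 and SWR1 type complex (-0.32) and the longest genes (-0.16) lower, and the shortest (0.94) and the single exon genes (0.6) higher, with adjusted p = 0.38 to 0.64 with an estimated correlation. With the background covariate the medians of ribosomal proteins (0.14), oxidative phosphorylation (0.03) and the longest genes (0.01) in Trl were above 0 and camera's direction turned. By library the ribosomal medians were -1.37, -0.34 and 0.22 and those of oxidative phosphorylation -0.77, -0.24 and 0.03. Of the 406 different genes of the 12 lists called (those by length or exons left out), 2 were higher and 18 lower, and 12 and 57 adjusted over the list alone. The rule also named tej (2.7, SE 0.4), Cyp4p2 (2.3, SE 0.36), pip (1.76, SE 0.48) and Rgk2 (1.76, SE 0.35) as higher and Csgalnact (-2.88, SE 0.25), 7SLRNA:CR32864 (-2.69, SE 0.66), Dhc98D (-2.2, SE 0.38) and hzg (-2.06, SE 0.24) as lower.

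The test called 379 genes in Trl, 94 higher and 285 lower, against 120 higher and 98 lower with DESeq2's size factors, which moved the median log2 fold change of all genes from 0.21 to 0.39. The Trl libraries had 101.3 to 171.7 reads outside features per 100 gene counts, against 79.3 to 92.4 in LexA, and with the background covariate 65 genes were called, 49 of them among the 379. The count ran from 34 (without LexA replicate 2) to 1190 (without Trl replicate 3), with 50 and 41 without Trl replicates 1 and 2 and 94 and 128 without LexA replicates 1 and 3. DESeq2 called 996, and the count was 4654 against the other 8 knockdowns, 1184 in a fit of only the 6 libraries, 760 with the replicate block and 140 with no filter on low counts.

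In Top1, ninaE was higher than in LexA (log2 fold change 0.97, SE 0.2, adjusted p 0.02), at 22700, 31500 and 23300 CPM against 12900, 15100 and 11500 CPM. Of the 64 called genes 27 were higher and 37 lower (edgeR). The increases were led by Cyp4p2 (2.88, SE 0.37), the immune peptide gene BomS2 (2.34, SE 0.38), Rgk2 (2.2, SE 0.36) and the odorant-binding protein gene Obp99b (2.16, SE 0.5), and the decreases by dpr21 (-2.88, SE 0.39), Csgalnact (-2.62, SE 0.25), the dynein gene Dhc98D (-2.59, SE 0.39) and hzg (-2.19, SE 0.24). Camera called 12 lists. Ribosomal proteins (median 0.59, adjusted p 2.3e-21), glycolysis (0.64, 6.6e-05), glia (0.46, 3.4e-04), oxidative stress (0.43, 1.0e-04), oxidative phosphorylation (0.33, 1.4e-06), other neurons (0.3, 0.0055), muscle (0.29, 0.045), the proteasome (0.21, 0.0043) and immunity (0.12, 0.0072) were higher. Synapse and excitability (-0.43, 1.0e-05), the rhabdomere (-0.21, 0.045) and the longest genes (-0.06, 0.047) were lower. Adjusted p was 0.52 or 0.81 with an estimated correlation. Of the 396 different genes of these lists (the longest genes left out), edgeR called 1 and DESeq2 4, all higher, with 49 higher and 10 lower at an unadjusted p under 0.05 and 1 adjusted over the list alone. The count was 31 without Top1 replicate 2, 42 without Top1 replicate 3, 29 and 40 without LexA replicates 2 and 3, 107 with the background covariate, 188 with DESeq2 and 204 in a fit of only the 6 libraries.

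In cnc, whose product is the fly homologue of the antioxidant regulator Nrf2, 18 genes were higher and 25 lower. Cyp4p2 (3.07, SE 0.37, adjusted p 2.6e-05), BomS2 (2.45, SE 0.37), Rgk2 (2.26, SE 0.36) and Cyp4p1 (2.17, SE 0.28) rose, and Csgalnact (-2.86, SE 0.24), dpr21 (-2.42, SE 0.38), l(2)41Ab (-1.89, SE 0.34) and the ankyrin gene Ank2 (-1.78, SE 0.37) fell. Camera called 9 lists, all higher: ribosomal proteins (median 0.53, adjusted p 2.8e-16), glycolysis (0.45, 0.0024), glia (0.35, 3.6e-04), immunity (0.33, 0.011), other neurons (0.29, 0.0049), oxidative phosphorylation (0.22, 5.7e-04), oxidative stress and glutathione (0.21, 0.0017), the unfolded protein response (0.17, 0.0024) and the proteasome (0.13, 0.0014). Each had adjusted p = 0.88 with an estimated correlation. The lists other than the unfolded protein response rested mostly on cnc replicates 1 and 3. In replicate 2 the medians were 0.14 for ribosomal proteins (1.01 and 0.37 in the others), 0.06 for glycolysis (0.83 and 0.49), 0.04 for immunity (0.39 and 0.38) and 0.03 for the proteasome (0.27 and 0.23). For the unfolded protein response they were 0.34, 0.18 and 0.13 in replicates 1, 2 and 3. Of the 349 different genes of these lists, edgeR called 1 higher and DESeq2 3 higher and 1 lower, with 28 higher and 1 lower at an unadjusted p under 0.05 and 4 higher adjusted over the list alone. Of 38 oxidative stress and glutathione genes, a set that cnc is known to regulate, edgeR called 0 and DESeq2 0, with 3 higher at an unadjusted p under 0.05, and GstS1, named first by the rule, had 0.7 (SE 0.23, adjusted p 0.36).

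In TH1, a subunit of the pausing factor NELF, 12 genes were higher and 18 lower. Cyp4p2 (2.84, SE 0.37), Cyp4p1 (1.91, SE 0.28), Rgk2 (1.71, SE 0.35) and Sec63 (1.01, SE 0.2) rose, and Dhc98D (-2.64, SE 0.39), Csgalnact (-2.5, SE 0.24), dpr21 (-1.97, SE 0.37) and hzg (-1.82, SE 0.24) fell. Camera called mitochondrially encoded proteins (median 0.63, adjusted p 4.7e-04), heat shock (0.49, 0.0017) and other neurons (0.36, 0.0021) higher. It called phototransduction (-0.3, 0.0042), the rhabdomere (-0.28, 0.0016), synapse and excitability (-0.25, 0.0015), transcription factors (-0.16, 0.0016) and autophagy and lysosome (-0.14, 0.011) lower. Each had adjusted p = 0.83 with an estimated correlation. Of the 185 different genes of these 8 lists edgeR called 0 and DESeq2 1, with 10 higher and 5 lower at an unadjusted p under 0.05. Of 21 heat shock genes 0 were called by edgeR over all genes and 1 by DESeq2, with 7 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone, and the heat shock medians of TH1 replicates 1, 2 and 3 were -0.25, 0.91 and 0.12. Without TH1 replicate 2 the heat shock median was 0.12.

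In Cdk12, a kinase of elongating RNA polymerase II, 6 genes were higher and 23 lower. BomS6 (2.3, SE 0.41), Cyp4p2 (2.04, SE 0.36) and the translation inhibitor gene Thor (1.69, SE 0.29) rose, and Cp7Fa (-2.85, SE 0.58), Csgalnact (-2.57, SE 0.24), nompB (-1.89, SE 0.34), hig (-1.71, SE 0.3) and the sterol-binding gene Npc2a (-1.64, SE 0.27) fell. Camera called mitochondrially encoded proteins (median 1.18, adjusted p 7.9e-09) and ribosomal proteins (median 0.53, adjusted p 1.7e-16, with 0.18, 0.69 and 0.78 by library) higher, and the rhabdomere (-0.23, 0.028), synapse and excitability (-0.16, 0.02), autophagy and lysosome (-0.15, 0.011) and transcription factors (-0.14, 0.026) lower, each with adjusted p = 0.83 with an estimated correlation. Of the 202 different genes of these 6 lists edgeR called 1 lower, and DESeq2 3 higher and 1 lower, with 23 higher and 5 lower at an unadjusted p under 0.05. Of 12 mitochondrial genes 0 were called over all genes by edgeR and 0 by DESeq2, with 7 higher at an unadjusted p under 0.05 and 7 adjusted over the list alone.

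In Taf1, a subunit of the initiation factor TFIID, 11 genes were higher and 11 lower. The zinc transporter gene ZnT77C had the largest increase named (5.42, SE 0.34, adjusted p 4.3e-11), at 107, 128 and 91.3 CPM against 1.99, 2.66 and 2.96 CPM in LexA. Cyp4p2 (2.39, SE 0.37), Cyp4p1 (1.47, SE 0.28) and the phosphodiesterase gene Pde11 (1.07, SE 0.2) also rose, and dpr21 (-2.6, SE 0.38), Csgalnact (-2.52, SE 0.24), bru2 (-1.59, SE 0.33) and Mbs (-0.91, SE 0.18) fell. Muscle markers were called lower by camera (median -0.89, adjusted p 3.6e-11, and adjusted p = 0.4 with an estimated correlation). Of 23 members 0 were called over all genes by edgeR and 0 by DESeq2, with 14 lower at an unadjusted p under 0.05 and 10 adjusted over the list alone. Camera also called the proteasome (0.29, adjusted p 1.3e-05), ribosomal proteins (0.21, 1.2e-04), the unfolded protein response (0.2, 0.0086) and oxidative phosphorylation (0.14, 0.032) higher, each with adjusted p = 0.99 with an estimated correlation. Of the 242 different genes of the 5 lists edgeR called 0 and DESeq2 0, with 14 higher and 15 lower at an unadjusted p under 0.05.

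In Spt6, a histone chaperone of elongation, 10 genes were higher and 6 lower. The prohibitin gene Phb1 (3.25, SE 0.26, adjusted p 6.3e-09), the dopa decarboxylase gene Ddc (3.13, SE 0.49), tej (2.89, SE 0.4) and BomS6 (2.11, SE 0.41) rose, and Csgalnact (-2.36, SE 0.24), nAChRalpha4 (-1.14, SE 0.24) and Mbs (-1, SE 0.18) fell. Phb1 (chromosome 2L, 19121345 to 19123869) and Ddc (2L, 19116483 to 19120306) are neighbours on BDGP6. Camera called 8 lists, all higher: ribosomal proteins (median 0.65, adjusted p 6.7e-28), fat body and hemocytes (0.48, 1.1e-04), glycolysis (0.48, 7.5e-04), glia (0.46, 1.2e-04), immunity (0.46, 0.0012), oxidative stress (0.28, 0.0012), oxidative phosphorylation (0.25, 9.2e-05) and the proteasome (0.18, 0.0022). Adjusted p with an estimated correlation was 0.78, or 0.96 for the proteasome, whose median was -0.05 in Spt6 replicate 1. Of their 333 different genes edgeR called 0 and DESeq2 2 higher, with 56 higher and 3 lower at an unadjusted p under 0.05 and 7 higher adjusted over the list alone. Of the 85 ribosomal protein genes edgeR called 0 and DESeq2 0, with 23 higher at an unadjusted p under 0.05.

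For the comparisons with few calls, the counts moved with the test and the libraries. DESeq2 called 125 genes in cnc, 78 in TH1, 117 in Cdk12, 76 in Taf1 and 57 in Spt6, where edgeR called 43, 30, 29, 22 and 16. For cnc the count was 20 and 28 without cnc replicates 1 and 2 and 25 and 27 without LexA replicates 2 and 3. For TH1 it was 19 without TH1 replicate 3 and 19 without LexA replicate 1. For Cdk12 it was 14 and 9 without Cdk12 replicates 2 and 3 and 16 and 11 without LexA replicates 2 and 3. For Taf1 it was 13 and 14 without Taf1 replicates 2 and 3 and 14 without LexA replicate 3, and for Spt6 it was 9 without Spt6 replicate 2 and 9 without LexA replicate 2.

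The same genes were called in many comparisons. Mbs (chromosome 3L, 16051959 to 16082026), which encodes a subunit of myosin phosphatase, and the neighbours Csgalnact (2R, 10249220 to 10255495) and CG12911 (2R, 10256686 to 10261276) were lower in all 9 knockdowns. CG12911 was chosen after its values were seen. Csgalnact stood at 72.8 to 97.8 CPM in LexA and at 8.55 to 19.7 CPM in the 27 other libraries, and Mbs at 798 to 1010 CPM against 272 to 552 CPM. Cyp4p2 was higher and dpr21 lower in 7 comparisons, and Cyp4p1 and Rgk2 were higher in 6.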

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

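Of the tests in this part, those of the label, the slope, the genes called in many comparisons, the neighbours, the share of photoreceptor nuclei and the file layout were chosen after the results were seen, and so were the background covariate and the Cdk12 reference. Reads that aligned to several places, a quantity outside the gene tests, stood above the LexA range of 17.7 to 21.7 per 100 gene counts in 12 libraries. They were 59.2, 94.5 and 76.9 in Spt5 replicates 1, 2 and 3 and 82.6, 72.9 and 73 in Cdk12 replicates 1, 2 and 3, and nearer LexA in dom replicate 1 (29.8), Spt6 replicate 1 (28.4), TH1 replicate 2 (22.6), Taf1 replicate 1 (33) and Trl replicates 1 and 2 (25.5 and 32.2). The Gal4 transgene stood above the LexA libraries in Cdk12 replicate 1 (11360 CPM, against 3903 to 8200 CPM) and below all 3 in every library of Spt5 (773.3 to 2765 CPM), dom (2032 to 2883 CPM), Trl (2184 to 3847 CPM) and cnc (2138 to 3050 CPM). The GFP transgene stood above the highest LexA library (22.57 CPM) in Top1 replicates 1 and 2 (27.77 and 35.99 CPM), in Taf1 replicate 3 (23.8 CPM) and in Spt6 replicates 1, 2 and 3 (22.7, 32.09 and 25.89 CPM), and below the lowest (10.1 CPM) in every library of dom (7.707, 7.815 and 8.234 CPM) and Trl (5.026, 9.696 and 6.944 CPM). Groups of 3 libraries were not tested for single libraries far from the others.

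Spt5 replicate 3 stood apart from Spt5 replicates 1 and 2, with 2765 Gal4 CPM against 773.3 and 856 and a median of 0.04 for markers of other neurons against 2 and 1.73. The trend with reads outside annotated features gave -52% of its difference in phototransduction genes, the wrong direction, and 41.9% of that in ribosomal protein genes, which argues against this background as the whole cause. A weaker form of the same effect cannot be told apart: the slope of its change on that of replicates 1 and 2 against LexA (6492 genes, which are not independent replicates) ran from -0.19 to 0.13 against the 8 other knockdowns, where other libraries against their group mates gave -0.25 to 0.23. Its medians against the shared LexA libraries lay on the side of replicates 1 and 2 in 15 of the 16 lists called. That count decides nothing, since replicate 3 took part in calling the lists. Several of its medians were also near 0, such as 0.01 for cone, pigment and corneal cells and 0.05 for glycolysis. Others were not, such as 0.84 for mitochondrially encoded proteins and 0.4 for heat shock. A wrong label or another fly line may be the source. Replicate 3 differed from its group mates by over 1 log2 unit at 15 of 28 genes that differ between groups. Spt5 replicates 1 and 2 did at 7 and 9, where replicate 3 is itself among the group mates. Replicates 1 and 2 differed from each other at 2 of these genes, and replicate 3 from replicates 1 and 2 at 14 and 15. Against its group mates, no library of the 8 groups other than Spt5 and dom exceeded 5, but the genes were chosen for a small spread within those 8 groups. This low count therefore follows in part from the choice. In dom, left out of the choice as Spt5 was, no library exceeded 2. Spt5 replicate 3 matched no group at these genes (0.93 from Cdk12 and from cnc, 1.01 from LexA, 1.5 from Spt5 replicates 1 and 2), and no swap was found. The effect in replicates 1 and 2 could itself move such genes, and a biological difference within the group was not tested.

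Genes called in many comparisons, such as Mbs and Csgalnact, may reflect the LexA libraries, differences between fly lines or a response shared by the knockdowns, and these cannot be told apart with LexA as the single control group. The same holds for lists that recurred. Against LexA, camera called ribosomal proteins higher in Spt5, dom, Spt6, Cdk12, Taf1, Top1 and cnc, and lower in Trl. It called synapse and excitability and the rhabdomere lower in Spt5, dom, TH1, Cdk12, Top1 and Trl. With the other 8 knockdowns in place of LexA, 1 of 27 calls of the genes called in all 9 comparisons was left, and 7 of 43 of those called in 5 to 7, but this follows from how the genes were chosen and decides nothing. In the 6 comparisons with fewest calls, 35 of 127 different genes called (27.6%) had another called gene within 20 kb, such as Phb1 and Ddc in Spt6 or Cyp4p1 and Cyp4p2 in cnc. Draws of as many tested genes matched in expression gave a median of 10 and at most 30 (permutation p 1.0e-04, the smallest these draws can give), as differences between lines in short stretches of the genome would need. Neighbouring genes can also share regulation, and the genotypes of the lines were not analysed here.

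In Spt5, photoreceptor genes were lower and genes of several other cell types higher. With the background covariate 17 of 17 phototransduction genes were still called lower, which argues against reads outside annotated features as the whole cause. Against Cdk12, which shares the file layout of Spt5, 14 of the 16 lists called in Spt5 passed the same way. Of the others, 1 kept its direction without passing and 1 turned. Of the 17 phototransduction genes 3 were still called, and 24 of the 30 list members were lower by sign. The median of this list was -0.78, where it was -0.92 against LexA, with a median SE of 0.33 in both. By the rule first set, so few calls left did not speak against the layout. A rule on the Cdk12 medians was added after these values were seen. The Cdk12 libraries themselves lay no lower than -0.21 against LexA, which argues against the layout as the whole cause unless Cdk12 knockdown offset it. A lower share of photoreceptor nuclei would raise the markers of all other types alike only if those types kept their proportions. The median of other neuron markers less that of muscle markers was taken per library (1.84, 1.22 and 0.34 in Spt5 replicates 1, 2 and 3, -0.52 to 0.42 in LexA). It was on average 1.13 higher in Spt5 (SE 0.37 between libraries, adjusted p 0.04 over 15 pairs of lists). Without Spt5 replicate 3 this was 1.53 (SE 0.37), and muscle genes at the levels of the neuron markers gave 1.18 (SE 0.4). But it was also 1.33, 0.85 and 0.68 in Taf1, where muscle markers had a median of -0.89, and 1.5, 0.14 and -0.22 in Trl. Proportions thus cannot be taken as kept, and the marker lists do not decide. The rule set first asked whether 13 photoreceptor genes fell alike. Their heterogeneity p was 0.17, which a lower share allows, or 3.1e-11 without Spt5 replicate 3. The test took genes of the same libraries as independent, and replicate 3 adds to the spread of several of them. The p of 0.17 therefore does not show that they fell alike. Without replicate 3 they fell unevenly, from -0.69 (ninaE, SE 0.2) to -2.58 (ninaC, SE 0.33), which an equal loss alone would not give. A lower share stays open, as do a change in the types that rose and the effect of Spt5 knockdown. Spt5 RNA itself was not called lower (log2 fold change -0.34, adjusted p 0.24).

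For each comparison the 6 libraries have 10 splits into 3 and 3, too few for a share under 0.1, and in each the real split was the 1 with the most genes. The highest count of any other split was 1620 for Spt5 (real 2450), 1 for dom (1543), 1 for Spt6 (16), 0 for TH1 (30), 0 for Cdk12 (29), 0 for Taf1 (22), 1 for Top1 (64), 1 for Trl (379), 0 for cnc (43) and 1100 for Spt5 against dom (1219). The splits with 1620 and 1100 genes put Spt5 replicates 1 and 2 together with 1 library of the other group, a structure of these samples that follows Spt5 replicate 3.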

How the results depend on the processing

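The background covariate and the Cdk12 reference were chosen after the results were seen; the other alternatives were not. The cause was not tested for any change below. With DESeq2's size factors, 100 list calls passed the same way and 4 kept their direction without passing. With 1 library left out these were 525 and 97, and 2 turned. With the background covariate they were 75 and 26, and 3 turned. With an estimated correlation the 104 list calls kept their direction and did not pass, and with fry 26 passed. Fry called 0 lists in Spt6, TH1, Cdk12, Taf1, Top1 and cnc. Its lowest adjusted p there was 0.53, 0.74, 0.75, 0.41, 0.38 and 0.75. Of 10 comparisons and 1 shared count, the replicate block moved 1 by over 1.5 times (Trl 760). Pairing of libraries by number was weak on average. The mean correlation was 0.05 for pairs of the same number (-0.62 to 0.67) and -0.02 for pairs of different numbers. Yet 15 of 30 libraries were closest to their own number, so some pairing cannot be excluded. Leaving out ribosomal RNA and mitochondrial genes moved none of the 11.

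With DESeq2's Wald test the counts were 2400 for dom, 57 for Spt6, 78 for TH1, 117 for Cdk12, 76 for Taf1, 188 for Top1, 996 for Trl, 125 for cnc, 1938 for Spt5 against dom and 1055 for genes changed the same way, Spt5 and dom. With only the 6 libraries compared they were 2 for Spt5, 2565 for dom, 73 for TH1, 106 for Cdk12, 113 for Taf1, 204 for Top1, 1184 for Trl, 20 for cnc, 369 for Spt5 against dom and 2 shared. With the background covariate they were 33 for Spt6, 52 for TH1, 50 for Cdk12, 37 for Taf1, 107 for Top1, 65 for Trl, 77 for cnc and 814 shared. With the other 8 knockdowns as the reference they were 88 for Spt6, 59 for Cdk12, 397 for Taf1 and 4654 for Trl. Trl had 218 with DESeq2's size factors and 140 with no filter on low counts, and Spt5 had 1003 with the Cdk12 reference, 863 of them among its 2450.

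With 1 library left out the counts ran from 244 (without Spt5 replicate 1) to 3726 (without Spt5 replicate 3) for Spt5, from 648 (without LexA replicate 2) to 1215 for dom, from 9 to 21 for Spt6, 19 to 23 for TH1, 9 to 29 for Cdk12, 13 to 23 for Taf1, 29 to 46 for Top1, 34 to 1190 for Trl, 20 to 38 for cnc, 624 to 2849 for Spt5 against dom and 74 to 1081 for genes changed the same way, Spt5 and dom. The target Spt5 was called lower with the background covariate (-0.44) and DESeq2 (-0.39), and Trl higher with DESeq2 (0.84) and the other 8 knockdowns (0.85).

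With the other 8 knockdowns as the reference, Csgalnact turned in Spt5 (0.02), dom (0.21), Spt6 (0.25), TH1 (0.1), Cdk12 (0.02) and Taf1 (0.08), Mbs in Spt6 (0.21) and Taf1 (0.31), Cyp4p2 in Cdk12 (-0.29) and Cyp4p1 in Taf1 (-0.14). With the Cdk12 reference, Csgalnact (0.01), Thor (-0.68), Npc2a (0.74) and the mitochondrially encoded list (-0.23) turned in Spt5. Camera's direction turned for heat shock genes in TH1 without TH1 replicate 2 (median 0.12, up to 1.06 with other libraries left out) and for the longest genes in Top1 without Top1 replicate 1 (median -0.04, between -0.1 and 0.01 with others left out). With the background covariate, ribosomal proteins (0.14), nuclear encoded oxidative phosphorylation (0.03) and the longest genes (0.01) turned in Trl, and the values given are medians. Of the named genes called, 0 of 90 in Spt5 and 35 of 76 in dom passed under every alternative. The value for Spt5 was nearly fixed in advance, since the fit of only the 6 libraries called 2 genes in all. The Cdk12 reference was tried for Spt5 alone, so the shares of Spt5 and dom are not comparable. Of the 90 genes, 26, 43 and 90 stayed called the same way without Spt5 replicates 1, 2 and 3. At the depth of these libraries and 3 replicates, the simulated test called 15.4% of genes changed 2-fold, and depth itself was not varied.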

Other observations

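In dom, genes of chromosome 4, the small and mostly heterochromatic chromosome of the fly, were called lower more often than others, but not beyond genes of like expression and length. All tests here were chosen after the result was seen. Of its 105 tested genes 22 were lower (21%), against 5.9% elsewhere (odds ratio 4.23, Fisher's exact p 2.1e-07, adjusted 5.1e-06 over 24 tests). Genes chosen after their values were seen included the kainate receptor subunit gene Ekar (log2 fold change -1.83, SE 0.38), dpr7 (-1.37, SE 0.24), the vesicle release genes Cadps (-1.21, SE 0.24) and unc-13 (-1.18, SE 0.25), Syt7 (-1.06, SE 0.22) and the transcription factor zfh2 (-0.92, SE 0.19). The chromosome's median in dom replicates 1, 2 and 3 was -0.42, -0.02 and -0.13, where that of all genes was 0.31, 0.04 and 0.16. The 22 became 10 without LexA replicate 2, 12 and 11 without dom replicates 2 and 3, and 35 in a fit of only the 6 libraries. The odds ratio ran from 3.18 to 5.85 over the alternatives and over the libraries left out. Drawn genes matched in expression (10 bins) and length (5 bins) gave a median of 16 lower genes and at most 30 in 10000 draws, and 22 or more with a permutation p of 0.08. In Spt5, 7 of the 105 were lower (odds ratio 1.24, p 0.52). The chromosome's median log2 fold change was -0.16 in dom, against 0.21 elsewhere. It also lay below that of genes elsewhere in Trl (-0.27 against 0.21) and Top1 (-0.29 against 0), with 2 genes called lower in each. In Taf1 (0.19 against -0.02) and Cdk12 (0.12 against 0.04) it lay above. A lower median was thus not particular to dom. An antisense RNA overlaps unc-13, and reads of the pair could not be told apart.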
